A study of Homo sapiens with 6 samples.

How the data were processed

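SET2 cells were plated in triplicate in 24-well plates and treated for 4 h with DMSO or 25 nM CA, and polyadenylated RNA was made into libraries with a mRNA Direct Micro kit and sequenced on an Ion Proton, per the labels' protocols. The labels give 3 libraries per treatment, numbered 1 to 3, and the groups and numbers were taken from the sample titles. Whether the sequencing kit kept strand, and whether the counting used it, is not given in the sources used here, so a gene and a transcript on the opposite strand cannot be told apart.

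The submitters' processing notes name BWA 0.7.5a, HTSeq 0.5.3p3, DESeq and the build hg19, without saying what each did or with which settings. The deposited table holds a normalised signal for 22095 Ensembl genes with their symbols, with 1 column per library. From the values, each deposited signal is the number of reads of a gene divided by a size factor of its library, with 1 added by the authors. No header says so. After that 1 was subtracted, 100% of the values in each library were whole multiples of 1 step, within 0.01 of a whole read. The largest deviation was 0.000252 of a read. The smallest sum of reads over the 6 libraries was 15, so genes with fewer reads are not in the table and were not analysed here. No row lacked a gene name, and 19 symbols belong to more than 1 identifier. No table of the authors' own comparison was analysed here.

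The design, fixed before the data were examined, foresaw edgeR's quasi-likelihood test for raw counts and limma for normalised values. Since the deposited values are normalised, limma (version 3.58.1, R 4.3.3) was the test, with an intensity trend and robust estimation, on log2(normalised count + 1), where the authors' added 1 had first been removed and replaced by this pseudocount of 1. Fold changes are on that scale, which understates changes of low genes. Genes with at least 10 normalised counts in at least 3 libraries were kept, which left 18632 genes and removed 3463. P-values were adjusted by Benjamini-Hochberg over the genes tested at a false discovery rate of 0.05, and the model had treatment as its only term. edgeR (4.0.16) on the recovered reads, added after the data were seen, called 333 genes higher and 36 lower, the 327 of limma among them.

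Recovered reads per library are 58897514, 71037069 and 65889898 for DMSO 1, 2 and 3 and 52721593, 68291482 and 62070992 for CA 1, 2 and 3. The common biological coefficient of variation from edgeR was 12.3%. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom between 12 and 79.3, so each counted as 1 replicate. Their log2 values had a Pearson correlation across genes between 0.986 and 0.992.

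The genes named in the text were set by a rule written before the data were examined. It takes the 10 largest rises and the 10 largest falls among called genes with a mean of at least 50 normalised counts and no overlap between groups, and up to 4 called members of each gene list by adjusted p. It also takes all members of the Mediator kinase module, and the 5 largest rises and 5 largest falls among called genes with a mean of at least 1000. It gave 74 genes, of which some are not reported here, and any other gene is said to have been picked out after its values were seen.

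The 33 gene lists were also written beforehand, from textbook knowledge. They cover the Mediator complex (kinase module, core subunits), blood lineages (haematopoietic transcription factors, megakaryocyte and platelet, erythroid, monocyte, stem and progenitor, mast cell and basophil), and signalling (STAT5, interferon, immediate early, NF-kB, TGF-beta and SMAD, Notch, Wnt, cytokine receptors). They also cover stress and metabolism (HIF1A, p53, cholesterol and SREBP, unfolded protein, heat shock, BCL2 family, oxidative phosphorylation), growth (G1/S, G2/M, MYC, ribosomal proteins, histones, chromatin readers) and other cell types (T and natural killer, B, fibroblast and endothelial, epithelial). The mast cell and basophil list was fixed as markers of other cell types too. Of 844 entries, 775 matched a symbol in the table. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 32 lists, and again with an estimated correlation and with fry. Lists share some genes, so their tests are not independent.

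Alternatives fixed beforehand were other scalings, other filters, other pseudocounts of 0.1 and 5, other thresholds, limma without the intensity trend, the DESeq2 (1.42.0) Wald test on recovered reads, the replicate number as a block, and leaving out each library in turn. Alternatives added after the data were seen were edgeR, TMM scaling, a correction for transcript length and GC content, and leaving out both libraries numbered 1. Transcript length and GC content came from GENCODE 29 on GRCh38 by stable gene identifier, with a transcript for 97.4% of the genes tested. That build differs from hg19, so no coordinates were taken from it. Comparing the median of each list with 10000 random lists of the same size and expression was chosen after the set tests were seen.

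The test was checked on simulated counts with the real genes' means and library sizes, in which 100 genes changed 1.5-fold and 100 changed 2-fold in each of 5 sets, all with a mean of at least 100 reads. limma recovered 69% of the first and 90% of the second, and 11% of its calls were false, above the nominal rate. edgeR gave 10.9% false calls over the same sets, and DESeq2 gave 19.8% in 1 simulated set. camera called a list shifted by 0.2 on the log2 scale in 5 of 5 sets and 0 of 31 unchanged lists in any of them. Genes were simulated independently of each other, so this check does not cover false passes from correlated genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.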

Results

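Polyadenylated RNA was sequenced from SET2 cells, an established human megakaryoblastic line from essential thrombocythemia, after 4 h with 25 nM cortistatin A (CA) or with DMSO, the vehicle. CA is a steroidal alkaloid that inhibits CDK8 and CDK19, the kinases of the Mediator complex, which connects transcription factors with RNA polymerase II. The comparison asked which transcripts differ in this line after 4 h of CA. Each group held 3 libraries from triplicate wells. No label says that the wells were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The reads assigned to the 22095 listed genes ranged from 58897514 to 71037069 per library in DMSO and from 52721593 to 68291482 in CA. Genes whose symbols start with MT- took 2.43% of the reads in DMSO library 1, 3.98% in DMSO 2 and 5.18% in DMSO 3. Their share was 4.4%, 4.61% and 4.7% in CA 1, CA 2 and CA 3. Mitochondrial transcripts under other symbols were not counted in these shares. Gene symbols are those of the deposited table, and positions are not given because the reference annotation used here is of another genome build than the authors' hg19.

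MYCN, a transcription factor of the MYC family, rose 3.42-fold after CA, from 72 ± 7.68 to 250.1 ± 43.2 normalised counts (mean ± SD, n = 3 per group). ANGPT2, a secreted ligand of the TIE2 receptor, rose 2.55-fold, from 979 ± 56.6 to 2496 ± 176 normalised counts. EGR1, a zinc finger transcription factor of the immediate early response, fell from 384 ± 43.3 to 157 ± 44 normalised counts. TXNIP, the thioredoxin-interacting protein, fell from 12687 ± 770 to 7483 ± 406. Across the 18632 genes tested, 295 were higher and 32 were lower in CA (limma, Benjamini-Hochberg false discovery rate under 0.05), so 90.2% of the 327 called genes were higher. The median fold of the higher genes was 1.38, and that of the lower genes, taken as DMSO over CA, was 1.35. At least 2-fold changes were called for 18 higher genes (11 without DMSO 2, 8 without CA 2) and for 1 lower gene, EGR1 (0 without DMSO 2 or CA 2, 2 without DMSO 1, 3 without CA 1, 5 without CA 3).

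The other genes with the largest rises among those with a mean of at least 50 normalised counts were FAM198B, PLK2, BHLHE22, SIM1, PRR9, CLVS2, IGFBP5 and RP11-361F15.2. PLK2, a polo-like kinase, had a log2 fold change of 1.46 ± 0.13 (standard error), and FAM198B one of 1.52 ± 0.20. The basic helix-loop-helix transcription factors BHLHE22 and SIM1 had log2 fold changes of 1.32 ± 0.18 and 1.26 ± 0.25. IGFBP5, a secreted binding protein of insulin-like growth factors, had one of 1.13 ± 0.19. PRR9, CLVS2 and the unnamed transcript RP11-361F15.2 lay between 1.11 and 1.18. With each of the 6 libraries left out in turn, RP11-361F15.2 was called in 0 fits, CLVS2 in 1 and SIM1 in 2.

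**Figure D1:**
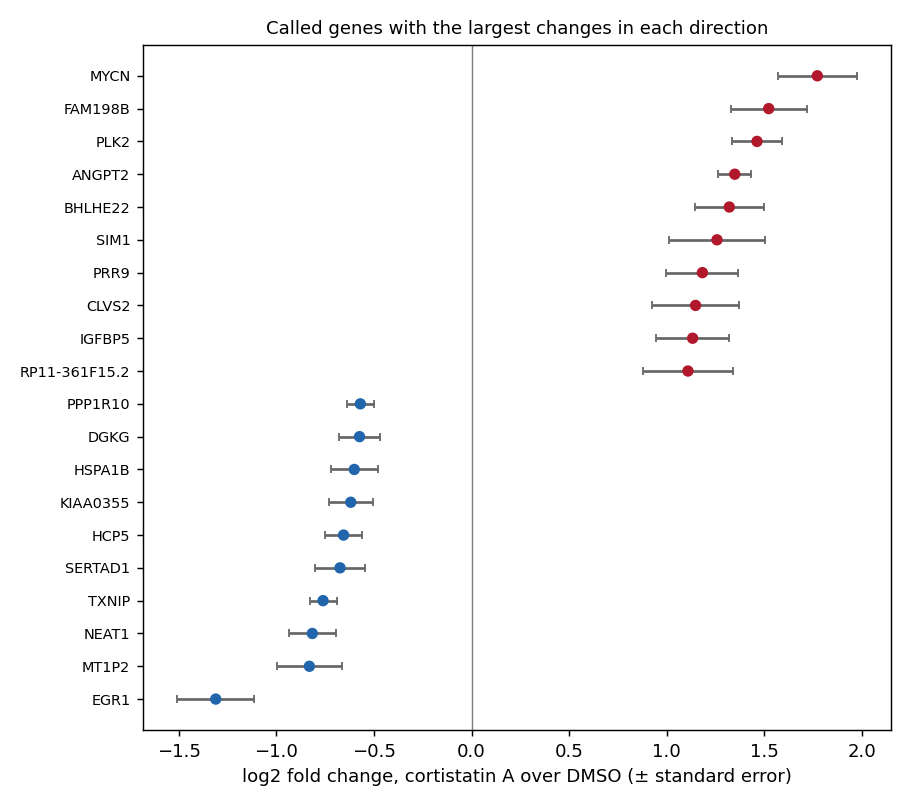
Each point is the log2 fold change of 1 gene, CA over DMSO (n = 3 libraries per group), and each bar its standard error; the genes are the 10 with the largest rise and the 10 with the largest fall among called genes with a mean of at least 50 normalised counts. The rises run from 1.11 (RP11-361F15.2) to 1.77 (MYCN), and EGR1 at -1.31 is the only fall beyond 1.

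Among abundant transcripts, with a mean of at least 1000 normalised counts, ENC1 rose from 8941 ± 209 to 18627 ± 236 normalised counts. RAB27B, a small GTPase of platelet granule secretion, rose 2.01-fold, and DHRS3, a reductase that acts on retinaldehyde, rose 1.99-fold. ID4, an inhibitor of basic helix-loop-helix factors, had a log2 fold change of 0.97 ± 0.09. NEAT1, the long noncoding RNA of paraspeckles, fell by 0.82 ± 0.12 on the log2 scale, and PPP1R10, a regulatory subunit of protein phosphatase 1, fell by 0.57 ± 0.07. Of the less abundant genes, SERTAD1 fell by 0.67 ± 0.13, KIAA0355 by 0.62 ± 0.11 and DGKG, a diacylglycerol kinase, by 0.57 ± 0.11. Some of the lower genes resemble or overlap others, and since reads shared between genes were not measured here, their assignment is uncertain. MT1P2 (log2 fold change -0.83 ± 0.17) is a metallothionein pseudogene, HCP5 (-0.66 ± 0.09) overlaps other transcripts, and HSPA1B (-0.60 ± 0.12) is nearly identical to HSPA1A, which was not called at -0.52 (adjusted p = 0.154, limma with Benjamini-Hochberg adjustment).

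All 327 called genes had CA libraries that did not overlap the DMSO libraries, as did 19.1% of all tested genes, where chance gives 10%. At an unadjusted p under 0.05 there were 2361 genes. Of the 67 called genes named by the rule fixed in advance, 31 stayed past the threshold with each of the 6 libraries left out in turn, among them MYCN, PLK2, ANGPT2, ENC1, RAB27B, TXNIP, HCP5 and PPP1R10, and 5 passed in none of these 6 fits. HSPA1B, DGKG, SIK1 and LEF1 passed in 1 of them, MT1P2, SERTAD1, KIAA0355, TRIB1, PIM2, VEGFA and AFF1 in 2, NEAT1, GP5 and BAMBI in 3, and PRR9, IGFBP5, CD34 and IL1RL1 in 4. Library total scaling ended the calls of SIM1, GP5, VCAN, PIM2, SIK1, CSF1, CFLAR, LEF1, PMAIP1, INSIG1, GATA2 and RP11-361F15.2, and both it and upper-quartile scaling those of VEGFA, MSMO1, AFF1 and FCER1A. EGR1 was lost without DMSO 2 or without CA 2, with a highest adjusted p of 0.0726 (limma, Benjamini-Hochberg). The counts depended on single libraries: 116 higher and 3 lower genes were called without DMSO 2, 91 and 4 without CA 2, 166 and 15 without CA 1, and 15 or 16 lower genes without DMSO 1 or DMSO 3. They also depended on the test: limma without its trend of variance on expression called 16 higher and 1 lower, the DESeq2 Wald test 85 lower, scaling by library totals 160 higher, and a correction for transcript length and GC content 71 lower.

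Of 38 haematopoietic transcription factors tested, 10 rose, 0 fell and 28 did not pass, and 19 rose when adjusted over the list alone. The median log2 fold change of the list was 0.21, and camera with a preset correlation of 0.01 gave an adjusted p = 2.12e-11 over the 32 lists tested, and adjusted p = 0.198 with an estimated correlation. GFI1B, a repressor needed for megakaryocyte and erythroid development, rose 1.62-fold (11762 ± 423 to 19037 ± 1112 normalised counts), and MYB, a regulator of haematopoietic progenitors, rose 1.47-fold. The Ikaros family members IKZF2 and IKZF1 rose 1.85-fold and 1.37-fold. GATA2 rose 1.3-fold, and MEF2C, LMO2, ETS1, GATA1 and GFI1, the further called members, which were picked out after their values were seen, had log2 fold changes between 0.34 and 0.59.

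Megakaryocyte and platelet genes had 4 of 31 members that rose and 0 that fell, with 10 that rose when adjusted over the list alone and a median log2 fold change of 0.15 (camera adjusted p = 1.9e-07, and adjusted p = 0.15 with an estimated correlation). They were RAB27B, ANGPT1 (log2 fold change 0.65 ± 0.08), PLEK or pleckstrin (0.46 ± 0.06) and the platelet glycoprotein GP5 (0.53 ± 0.10). Of 32 erythroid genes, 2 rose and 0 fell, among them HEMGN, a nuclear protein of blood cells (0.77 ± 0.12). Adjusted over the list alone, 6 rose and 1 fell (camera adjusted p = 0.0015, and adjusted p = 0.198 with an estimated correlation). Of 8 stem and progenitor cell genes, the receptor KIT (0.47 ± 0.06) and the surface protein CD34 (0.43 ± 0.07) rose. Of these 8, 4 rose when adjusted over the list alone (camera adjusted p = 0.000563, and adjusted p = 0.158 with an estimated correlation).

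KIT was also a member of the mast cell and basophil list and of the list of cytokine and growth factor receptors. In the first, 3 of 12 members rose. They were KIT, GATA2 (log2 fold change 0.38 ± 0.07) and the IgE receptor subunit FCER1A (0.34 ± 0.07). In the 6 fits with a library left out, KIT was called in 6, GATA2 in 2 and FCER1A in 1, and FCER1A was not called with upper-quartile (adjusted p 0.0604, limma) or library total scaling (0.108). Adjusted over the list alone, 6 rose (camera adjusted p = 6.82e-05, and adjusted p = 0.15 with an estimated correlation). In the second, KIT and IL1RL1 (0.44 ± 0.07), the interleukin 33 receptor, rose among 26 members. There, 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.000294, and adjusted p = 0.265 with an estimated correlation).

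**Figure D2:**
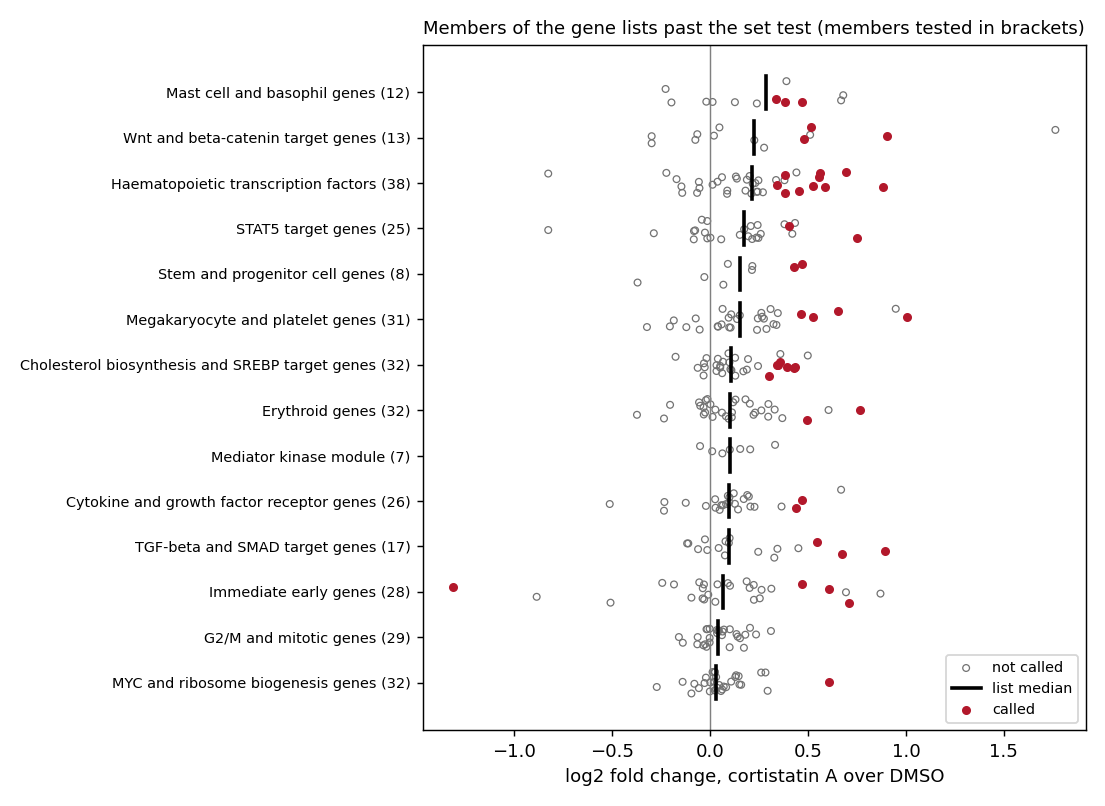
Each point is the log2 fold change (CA over DMSO) of 1 member of a gene list, filled where the gene was called, and each vertical bar is the median of the list; the 14 lists past the set test with a preset correlation are shown. The medians run from 0.03 for the MYC and ribosome biogenesis list to 0.29 for the mast cell and basophil list, and under library total scaling the medians of the MYC and ribosome biogenesis list (-0.03) and of the G2/M list (-0.02) lie below 0.

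Genes of cholesterol biosynthesis and other targets of SREBP transcription factors had 7 of 32 members that rose and 0 that fell, with 11 that rose when adjusted over the list alone (camera adjusted p = 1.98e-07, and adjusted p = 0.158 with an estimated correlation). SQLE, the squalene epoxidase, had a log2 fold change of 0.43 ± 0.06, the fatty acid desaturase SCD one of 0.36 ± 0.06, INSIG1 one of 0.39 ± 0.07 and MSMO1 one of 0.44 ± 0.09. DHCR7, picked out after its value was seen, also rose, with one of 0.35. With each of the 6 libraries left out in turn, SQLE was called in 6 fits, SCD in 4, INSIG1 in 1 and MSMO1 in 0.

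Of 17 TGF-beta and SMAD target genes, 3 rose and 0 fell, and 5 rose when adjusted over the list alone. ID2 (log2 fold change 0.90 ± 0.09), TGIF1 (0.55 ± 0.07) and the decoy receptor BAMBI (0.67 ± 0.12) passed over all genes (camera adjusted p = 0.000294, and adjusted p = 0.28 with an estimated correlation). Among 13 Wnt and beta-catenin target genes, the receptor TNFRSF19 (0.90 ± 0.07), the hyaluronan receptor CD44 (0.51 ± 0.07) and the transcription factor LEF1 (0.48 ± 0.10) rose. Of these 13, 5 rose when adjusted over the list alone (camera adjusted p = 0.000789, and adjusted p = 0.198 with an estimated correlation). Of 25 STAT5 target genes, TRIB1 (0.75 ± 0.14) and the kinase PIM2 (0.40 ± 0.08) rose. Of these 25, 4 rose when adjusted over the list alone (camera adjusted p = 0.00994, and adjusted p = 0.467 with an estimated correlation). The STAT5 list was lost without CA 1 (adjusted p = 0.114, camera) and by fry (0.141).

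Immediate early genes moved in both directions: FOSL2 (log2 fold change 0.71 ± 0.08), MYC (0.61 ± 0.07) and SIK1 (0.47 ± 0.09) rose and EGR1 fell among 28 members, and 6 rose and 2 fell when adjusted over the list alone. The list had a camera adjusted p = 0.0381, and adjusted p = 0.561 with an estimated correlation, and it did not pass without DMSO 1 (0.107), CA 1 (0.206) or CA 2 (0.103), without both libraries numbered 1 (0.327), with a mean of at least 50 (0.0628) or by fry (0.274). MYC rose from 43761 ± 715 to 66793 ± 5547 normalised counts and was the 1 called gene of the 32 on the MYC and ribosome biogenesis list, of which 4 rose when adjusted over the list alone (camera adjusted p = 0.0231, and adjusted p = 0.723 with an estimated correlation). That list did not pass without DMSO 2 (0.272), DMSO 3 (0.152) or CA 1 (0.121), with library total scaling (0.171), with a mean of at least 50 (0.06) or by fry (0.412). Of 29 G2/M and mitotic genes, 0 were called by limma, over all genes or adjusted over the list alone (6 at an unadjusted p under 0.05; 0 by edgeR and DESeq2). The camera adjusted p of 0.0358 became 0.324 with an estimated correlation and exceeded 0.05 without DMSO 2 (0.051), DMSO 3 (0.166), CA 1 (0.154) or CA 2 (0.0556). It did so too with upper-quartile (0.0718) and library total (0.258) scaling, a mean of at least 50 (0.072), the length and GC correction (0.148), without both libraries numbered 1 (0.0663) and by fry (0.145). The median log2 fold changes of these last 2 lists were 0.03 and 0.04, and those of 33% and 69.4% of 10000 random lists matched on size and expression were lower.

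**Figure D3:**
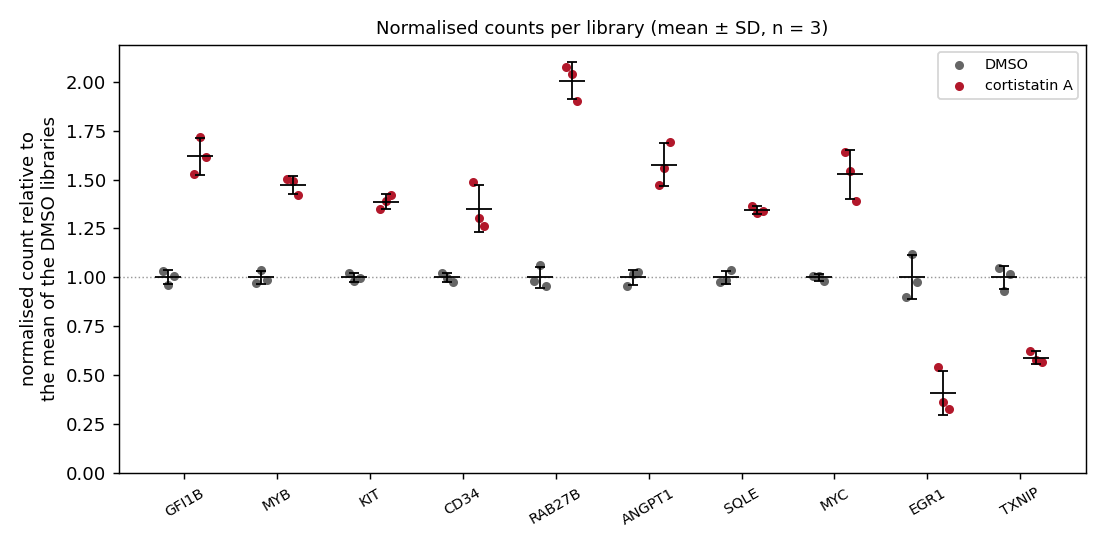
Each point is the normalised count of 1 library relative to the mean of the DMSO libraries, for 10 genes; bars are mean ± SD (n = 3 per group) and the vertical axis starts at 0. The CA libraries lie between 1.26 (CD34) and 2.08 (RAB27B) for the 8 genes that rose, and between 0.33 and 0.63 for EGR1 and TXNIP.

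No transcript of the Mediator kinase module, the complex part that holds the targets of CA, was called. CDK8 had a log2 fold change of 0.21 ± 0.08 (adjusted p = 0.296, limma with Benjamini-Hochberg adjustment) and CDK19 one of -0.05 ± 0.07, and the values were 0.15 ± 0.07 for cyclin C (CCNC), 0.06 ± 0.06 for MED12, 0.33 ± 0.10 for MED12L, 0.10 ± 0.08 for MED13 and 0.01 ± 0.06 for MED13L. Adjusted over the list alone, 0 of the 7 passed, 3 had an unadjusted p under 0.05 in limma, and edgeR and DESeq2 called 0. The module's set test passed with a preset correlation (camera adjusted p = 0.0432) and gave adjusted p = 0.538 with an estimated correlation, and it did not pass without DMSO 1 (0.17), DMSO 3 (0.0935), CA 1 (0.188) or CA 2 (0.0815), under upper-quartile scaling (0.0685) or under library total scaling (0.152). Nor did it pass with a mean of at least 50 (0.0727), the length and GC correction (0.145), without both libraries numbered 1 (0.388) or by fry (0.225). Of 26 core Mediator subunits, limma called 0 (2 at an unadjusted p under 0.05; 1 each by edgeR and DESeq2), and 1 rose when adjusted over the list alone (median log2 fold change 0.05, -0.01 under library total scaling; camera adjusted p = 0.374).

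The remaining lists did not pass the set test, and single members did. In the NF-kB response list of 22 genes, CSF1 (log2 fold change 0.41 ± 0.08) and CFLAR (0.35 ± 0.07) rose while ICAM1 (-0.43 ± 0.08) and TNFAIP2 (-0.44 ± 0.09) fell, and adjusted over the list alone the counts were again 2 and 2 (camera adjusted p = 0.584). With each of the 6 libraries left out in turn, TNFAIP2 was called in 0 fits, ICAM1 and CFLAR in 1 each and CSF1 in 2. Among 42 interferon response genes, RSAD2 (0.60 ± 0.08) and GBP4 (0.44 ± 0.06) rose, also when adjusted over the list alone (camera adjusted p = 0.843). VCAN, which encodes the proteoglycan versican, rose (0.93 ± 0.18) as the 1 called gene of 22 monocyte, macrophage and granulocyte genes, also when adjusted over the list alone (camera adjusted p = 0.0868), but was called in 0 of the 6 fits with a library left out. The list passed with no filter on low values (camera adjusted p = 0.0221) and by fry (0.0256), and had adjusted p = 0.28 with an estimated correlation. HES1 rose (0.59 ± 0.07) among 9 Notch target genes, with 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.843). VEGFA rose (0.38 ± 0.08) among 26 HIF1A target genes, also when adjusted over the list alone (camera adjusted p = 0.714). The amino acid transporter SLC7A5 rose (0.50 ± 0.08) among 28 unfolded protein and integrated stress response genes, also when adjusted over the list alone (camera adjusted p = 0.923).

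Of 15 BCL2 family genes, the BH3-only genes BCL2L11 (log2 fold change 0.53 ± 0.08) and PMAIP1 (0.50 ± 0.09) rose, with 3 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.923). PMAIP1, called in 0 of the 6 fits with a library left out, was also the 1 called member of 25 p53 target genes, of which 2 rose when adjusted over the list alone (camera adjusted p = 0.446). The elongation factor ELL2 (0.58 ± 0.08) and AFF1 (0.41 ± 0.09) rose among 25 chromatin readers and transcription kinases, with 2 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.884). HSPA1B fell among 17 heat shock genes, of which 2 fell when adjusted over the list alone (camera adjusted p = 0.488). None of 32 G1/S and DNA replication genes (camera adjusted p = 0.884), 45 cytosolic ribosomal protein genes (0.753), 31 oxidative phosphorylation genes (0.714) or 19 replication-dependent histone genes (0.714) was called by limma. At an unadjusted p under 0.05 these lists had 4, 9, 5 and 6 genes, and edgeR called 0 and DESeq2 called 2 histone genes. Adjusted over the list alone, 1 histone gene was higher and 1 lower, and 0 genes of the other 3 passed. Polyadenylated RNA holds little of most histone transcripts.

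Of the markers of other cell types, 0 were called among 7 T and natural killer cell, 4 B cell, 8 fibroblast and endothelial and 6 epithelial genes, and 1 epithelial gene rose when adjusted over the list alone (camera adjusted p of 0.566 for T and natural killer cell, 0.374 for fibroblast and endothelial and 0.923 for epithelial markers; the B cell list was too short to test). At an unadjusted p under 0.05 in limma there was 1 T and natural killer cell, 1 fibroblast or endothelial and 1 epithelial gene, and edgeR and DESeq2 called 0 of these markers. The mast cell and basophil list, given above, was also fixed beforehand among the markers of other cell types. It had 3 of 12 members called (camera adjusted p = 6.82e-05, and adjusted p = 0.15 with an estimated correlation). Directions differed between measures in some lists that did not pass. The interferon, BCL2 family and chromatin lists had median log2 fold changes of -0.03, -0.08 and -0.01 while camera's direction was up. T and natural killer cell markers had a median of 0.09 and a mean of -0.04, epithelial markers a median of 0.01, a mean of -0.03 and a camera direction of down, and ribosomal protein genes a median of 0.02 and a mean of -0.003. The medians of the p53 target, G1/S, ribosomal protein, oxidative phosphorylation and epithelial lists turned negative under library total scaling.

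In all, 14 of the 32 lists passed the set test with a preset correlation, 14 upward and 0 downward, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.15 and 7 lists had an unadjusted p under 0.05. Without CA 1, 9 lists passed. By fry, which asks whether a list's genes move one way without comparing them with other genes, 10 lists passed, 9 of them among the 14. Calls also depended on expression level: with the genes in 4 groups of 4658 by mean expression, 5, 32, 90 and 168 were called higher from the lowest group to the highest, and 0, 5, 17 and 10 lower. The median standard error of the log2 fold change went from 0.40 in the lowest group to 0.07 in the highest, and the median log2 fold change from -0.13 to 0.04.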

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

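The tests by edgeR, with TMM scaling, with the correction for transcript length and GC content and without both libraries numbered 1 were chosen only after the result was seen. The 327 called genes kept their direction under every alternative that gave them a value. All 327 stayed past the threshold by edgeR and with TMM scaling, 323 of 323 by the DESeq2 Wald test, 277 with upper-quartile scaling, 191 with library total scaling and 14 by limma without the intensity trend. The 295 higher genes became 160 with library total scaling, 16 without the intensity trend and 129 at a false discovery rate of 0.01. With 1 library left out they numbered 91 (CA 2), 116 (DMSO 2), 166 (CA 1), 198 (DMSO 3), 210 (CA 3) or 227 (DMSO 1). The 32 lower genes became 85 by DESeq2, 1 without the intensity trend, 71 with the length and GC correction, 4 at a false discovery rate of 0.01 and 64 at 0.1, and 3 (without DMSO 2) to 24 (without CA 3) with 1 library left out. The 18 higher genes of at least 2-fold became 9 without the intensity trend and 8 (without CA 2) to 15 with 1 library left out. The 1 lower gene of at least 2-fold became 4 by DESeq2, 2 by edgeR, 2 with the length and GC correction, 3 without both libraries numbered 1, and 0 (without DMSO 2 or CA 2) to 5 (without CA 3). Fewer libraries were fitted in the left-out fits, and otherwise the cause was not tested. The 14 lists past camera became 0 with an estimated correlation and 9 (without CA 1) to 14 with 1 library left out. The replicate number as a replicate block gave 601 higher, 324 lower, 35 higher of at least 2-fold and 11 lower of at least 2-fold, so 65% of its calls were higher, against 90.2% without it. It also called MED12L (log2 fold change 0.33, limma adjusted p 0.0456), and the Mediator kinase and G2/M lists missed the camera threshold under it (adjusted p 0.0505 for each). No other called gene named in the text and no other list past camera changed its call under it. Deviations of same-numbered libraries from their group means correlated at 0.401, -0.087 and 0.516 over 13420 genes, and the numbers were not taken to pair the libraries. DMSO 2 and CA 2 did not correlate best with each other. The deviations' rank correlation with transcript length fell with the number in both groups. It was 0.257, 0.04 and -0.332 in DMSO 1 to 3 and 0.305, 0.006 and -0.365 in CA 1 to 3. With number 2 between the others there, its low correlation is weak evidence against pairing. With GC content, number 2 went opposite ways (-0.201 in DMSO, 0.258 in CA). Whether the numbers pair the libraries stays open, and with it the choice between both fits. Some lists that did not pass the camera test turned in direction, each still without passing (Benjamini-Hochberg adjusted p). The unfolded protein list turned under the replicate block (0.96) and without both libraries numbered 1 (0.32), with 0.349 to 0.855 over the 6 left-out fits. The G1/S list turned with upper-quartile scaling (0.905), library total scaling (0.559) and a mean of at least 50 (0.986), with 0.194 to 0.88 over the left-out fits. The oxidative phosphorylation list turned with library total scaling (0.946), with 0.181 to 0.885 over the left-out fits. The BCL2 family list turned by fry (0.97; 0.587 to 0.88 over the left-out fits). The chromatin list turned with upper-quartile (0.99) and library total (0.946) scaling, the length and GC correction (0.974) and without both libraries numbered 1 (0.523), with 0.271 to 0.862 over the left-out fits. The histone list turned with a mean of at least 50 (0.899) and without both libraries numbered 1 (0.0663), with 0.159 to 0.855 over the left-out fits. The epithelial list turned with library total scaling (0.965), no filter (0.819), without both libraries numbered 1 (0.767) and by fry (0.897), with 0.735 to 0.888 over the left-out fits. The interferon, HIF1A target and ribosomal protein lists turned only in left-out fits, with ranges of 0.517 to 0.939, 0.405 to 0.971 and 0.206 to 0.851. The log2 fold change of MED13 was -0.021 without both libraries numbered 1. That of MED13L was -0.014 with upper-quartile scaling, -0.051 with library total scaling, -0.025 with the length and GC correction, -0.043 without both libraries numbered 1 and -0.02 to 0.052 with 1 library left out. Of the 67 called genes named in the text, 59 lost their call without the intensity trend, 17 with library total scaling, 4 with upper-quartile scaling, 10 without both libraries numbered 1, 2 with the length and GC correction (MT1P2 at -0.58, adjusted p 0.0562, and HSPA1B at -0.58, 0.0728, by limma), 1 with a mean of at least 50 (AFF1, 0.0507), and 15 (without DMSO 1) to 36 (without CA 2) with 1 library left out. The 4658 least expressed genes gave 5 of the calls and had a median standard error of 0.40, and whether fewer of them changed was not tested.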

Other observations

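The tests of scaling, of transcript length and GC content on the calls and on the listed factors, of edgeR and DESeq2 on other splits, and of 4 further gene groups were chosen only after the result was seen. The genes of the next paragraphs were picked out after their values were seen. Of 29 genes of BMP signalling, 9 rose and 0 fell after 4 h of CA, among them the ligand BMP6 from 2947 ± 101 to 5037 ± 465 normalised counts (mean ± SD, n = 3 per group), the secreted regulator BMPER 1.69-fold, and the responsive genes ID4 1.96-fold and ID2 1.86-fold. FST, which encodes the activin antagonist follistatin, GDF11, BAMBI and SOSTDC1 had log2 fold changes of 0.43, 0.44, 0.67 and 0.57. BMP2 went from 7.35 ± 4.02 to 55.3 ± 9.03 normalised counts, a low level at which the fold is uncertain. ID1 and ID3, 2 further responsive genes, were not called, at -0.03 ± 0.07 and -0.11 ± 0.13. BMP8A, CHRD and ACVR2A were not called either, at -0.85 ± 0.36, -0.59 ± 0.29 and -0.37 ± 0.21.

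Of 18 genes of retinoid metabolism and receptors, the dehydrogenases DHRS3 and DHRS9 and the retinoic acid hydroxylase CYP26B1 rose, with log2 fold changes of 0.99 ± 0.07, 0.73 ± 0.09 and 1.09 ± 0.14. The metallothionein MT2A fell by 0.37 ± 0.08, and MT1X, at -0.49 ± 0.11, was not called. Of 32 glycan and sulphation transferases, 9 rose, among them B3GNT5 (0.67 ± 0.07) and CHST2 (0.56 ± 0.06). Other abundant genes that rose were the water channel AQP1 (0.94 ± 0.06), the sphingosine 1-phosphate receptor S1PR1 (0.90 ± 0.07), the prostaglandin receptor PTGER3 (0.79 ± 0.06) and the transcriptional regulators LMO4 (0.86 ± 0.08), CITED2 (0.68 ± 0.06) and SOX4 (0.56 ± 0.06). A hypothesis is that whole groups may have moved. With the genes that prompted them left out, the smallest camera p over the 4 groups was 0.218, which leaves open whether the other members moved.

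More genes were higher than lower in CA, 90.2% of 327. If scaling between libraries had made this, another scaling should have evened it, but the lowest share of higher genes over 4 other scalings was 80.4%, with library totals (median-of-ratios factors equal the authors' and moved nothing). After the correction for transcript length and GC content the share was 83.6%, so these tables argue against scaling and that trend as the whole cause. After thinning every library to 52721593 reads it was 91%. The deepest library held 71037069 reads, so thinning could hardly have changed the share and cannot decide on read depth. The median log2 fold change went from -0.13 in the lowest expression group to 0.04 in the highest, and whether this trend adds to the share was not tested. CA may raise more transcripts than it lowers at 4 h in this line, which is a hypothesis from the same data, and how the wells were handled is not given and stays open. With 1 library left out the share was at least 89.7% and the counts moved (91 higher and 4 lower without CA 2, 116 and 3 without DMSO 2, 166 and 15 without CA 1, 15 and 16 lower without DMSO 1 and DMSO 3). The share was lower than any of these with the replicate number as a block, as given above, and whether the numbers pair the libraries stays open.

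The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of 10, gave 295 higher, 32 lower, 18 higher of at least 2-fold and 1 lower of at least 2-fold, and the highest of the other splits gave 0 for each in limma. Every other split has more libraries of 1 treatment on each side, so it holds part of the treatment difference. The rest of that difference adds to the spread within its sides, which lowers its calls. The other splits are therefore not free of the treatment, for genes or for lists. At an unadjusted p under 0.05 the other splits gave 303 to 2399 genes, and edgeR called up to 4 and DESeq2 up to 576. That highest split set DMSO 1, CA 1 and CA 2 against the other libraries, and its 2399 genes and 576 DESeq2 calls compare with 2361 and 517 for the real split, so the libraries hold a structure besides the treatment. For the gene lists past camera, the real split gave 14 lists and the highest other split 11, with DMSO 1, DMSO 3 and CA 3 on one side. For 3 of the 14 lists another split gave a smaller camera adjusted p than the real one: 0.000106 against 0.0231 for the MYC and ribosome biogenesis list, 0.00637 against 0.0432 for the Mediator kinase module and 0.00818 against 0.0381 for immediate early genes. Most of the 14 lists also passed in other splits. The megakaryocyte, cholesterol and MYC lists did so in 3 splits each. The STAT5, immediate early, TGF-beta, Wnt and cytokine receptor lists did so in 2, and the erythroid, mast cell and Mediator kinase lists in 1. The stem and progenitor and G2/M lists passed in 0 other splits.

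The haematopoietic transcription factors had a median log2 fold change of 0.21. If their expression level alone had made this, random lists of the same expression should reach it, but 100% of 10000 such lists had a lower median and the highest of them was 0.13. The megakaryocyte, STAT5 and mast cell lists also had 0 random lists as high. After the correction for transcript length and GC content the median of the transcription factors was 0.223 (SD 0.039). These tables argue against expression level and that trend as the whole cause for the transcription factors. A candidate explanation is that CA raises GFI1B, MYB, IKZF1 and related factors together, but camera gave an adjusted p of 0.198 with an estimated correlation, against a range of 7.58e-13 to 0.198 over the alternatives. The list also passed camera in 4 of 9 other splits (smallest adjusted p 1.61e-06, against 2.12e-11 for the real split). Those splits hold part of the treatment difference, so their passes cannot tell an effect of CA from correlation among its genes between libraries. Such correlation stays open.

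Libraries of the same number deviated together for numbers 1 and 3, with a mean correlation of 0.459. After the correction for transcript length and GC content it was 0.288 (bootstrap SD 0.0129), between the bounds set beforehand, so a shared trend on length and GC content could account for part of it and cannot be told apart from other shared handling. Without the 13 genes named MT- and the 100 genes that follow them it was 0.463 (SD 0.0099). These are few of the 13420 genes compared, so leaving them out could hardly have lowered the correlation. That test therefore cannot decide whether mitochondrial transcripts are the cause. No biological explanation was tested, since the labels give none for the numbers.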
